A study of Mus musculus with 16 samples.

How the data were processed

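Total RNA of 16 osteogenic cultures of mouse bone marrow stromal cells, grown for 7 days, had been hybridized to an Illumina mouse expression BeadChip after biotin labelling. Per the labels, 8 cultures were wild type and 8 were Hdac3 CKO, in which Cre recombinase under the Osterix promoter removes Hdac3 from cells of the osteoblast lineage. All animals had a mixed CD1 and C57BL6 background. The labels do not say how many animals gave the cells, whether cultures were pooled, or on which days they were grown.

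The deposited values are probe intensities, made by the authors on a linear scale and quantile normalized across the 16 arrays. The highest intensity was 37892 on each array, the lowest 53.1 on 15 arrays and 54.2 on WT44, and the median 97.1 to 97.2, and no array was normalized again. The lowest intensity lies well above 0, so background was not removed down to 0, and fold changes of dim probes are compressed. The software, the background treatment and any filter are not given in the sources used here, and no detection p-values were used. Intensities were floored at 16 and log2 transformed. All 25697 probes were tested. Of these, 23978 carried 1 gene symbol and 1719 are unnamed here. Symbols of the 2016 platform annotation were updated through their Entrez gene identifiers to the GRCm38.p6 RefSeq gene table, which matched 23962 probes, and the probes covered 16593 genes. Of each gene with over 1 probe (4777 genes), the brightest over all arrays stood for the gene in the list tests.

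Arrays are named by genotype and the number in their title, such as WT13 and CKO15. These numbers fall into 5 runs of neighbours, a new run starting after a gap over 4: run 1 (5 and 7), run 2 (13 to 16), run 3 (21 to 24), run 4 (30 and 32) and run 5 (42 to 47). Each run holds as many wild type as Hdac3 CKO arrays, 1 of each in runs 1 and 4 and 2 of each in the others. The labels do not say what a number marks.

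The genotype difference (Hdac3 CKO minus wild type) was tested at every probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 over all probes as the threshold. The comparison named as the principal one had no covariate. The same fit with the 5 runs as a fixed block, also decided in advance, is given beside the first, because arrays of 1 run resembled each other. Values are mean log2 intensities with the SD over 8 arrays per genotype, differences carry their standard error (SE), and intervals are 95% confidence intervals. Exact permutation tests (two-sided) of single genes used all 12870 arrangements of the arrays, or all 864 that keep the genotype balance of every run. The p-values measure only the spread between these arrays, since the labels do not say which arrays come from separate animals. The number of arrays limits the precision.

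A total of 27 gene lists (409 genes, 367 measured, 1 of them in 2 lists) was fixed before the data were examined, as were the tests, the other processing settings and the rule for naming genes. The lists are lipid storage, adipocyte, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, glucocorticoid metabolism and response, osteoblast, osteoclast-regulating factors, Wnt signalling, TGF-beta and BMP signalling, extracellular matrix, histone deacetylases and Hdac3 corepressors, circadian clock, p53 and DNA damage, cell cycle, interferon response, cell stress, chondrocyte, macrophage, osteoclast, neutrophil, lymphocyte, mast cell, erythroid and megakaryocyte, endothelial, smooth muscle and pericyte, and skeletal muscle. The lipid storage, adipocyte and glucocorticoid lists were chosen partly from what is known of the study. Each list was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over the 27 lists, with fry beside them. Members of a list were also counted when adjusted over the list alone.

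Named genes are Hdac3, 15 genes named whatever they show (Runx2 among them, not analysed here), up to 12 genes per direction with the largest change among those past the threshold (single symbol, mean above the median probe in at least 1 genotype, 1 probe per gene, no clone or predicted names), and up to 4 members per list with the smallest p. Where no probe passed, the 10 genes per direction with the smallest p were taken and are reported as not passing. Genes named outside this rule were chosen after their values were seen.

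The code was tested on simulated data of the same shape with 50 changed probes at each size. Without a block it recovered 12% of log2 changes of 0.25, 66% of 0.5 and 92% of 1, with 1 false call. With the runs as a block the shares were 26%, 92% and 100%, with 8 false calls. None of 27 lists without a change was called in either fit. The changed probes of all sizes were added together and only among probes brighter than the median, which eases the adjusted threshold. These shares therefore do not give the power of the real comparison. Without a block the real Hsd11b1 difference of log2 1.57 had a limma adjusted p of 0.800. The simulated genes varied independently of each other, so the simulation does not show how the list test behaves when genes of a list vary together.

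Alternatives were repeated quantile normalization, median centring, filters on dim probes, other eBayes options, array weights, other floors, a normexp background step with an offset of 50, a rank test, other thresholds, leaving out each array, blocks by run (fixed or random) or by accession order, and the mean of all probes of a gene. Added after the data were seen were all alternatives run together with the run block, leaving out a run, the means of each run and genotype as 5 pairs, the intensity of the Y-linked gene Eif2s3y as a covariate, the mean of the macrophage markers as a covariate with and without Fcer1g, leaving out the wild type arrays of run 2, and a factor for these 2 arrays, which lack Y-linked RNA. Beside the run block this factor takes run 2 out of the genotype difference, as leaving out run 2 does. A sex covariate had been set down for the case that both sexes occur in both genotypes, and was not run in that form because only wild type held arrays without Y-linked RNA. The lists named acute phase, lysosome, ribosome biogenesis and Hox genes were also added then. Other splits of the 16 arrays, 100 with the real one, were drawn with a fixed seed, and genotype was also exchanged in whole runs (16 ways with the real one). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.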

Results

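Gene expression was measured in osteogenic cultures of mouse bone marrow stromal cells to ask how loss of the histone deacetylase Hdac3 from cells of the osteoblast lineage changes their transcripts. An Illumina mouse expression BeadChip was hybridized with RNA of 8 wild type and 8 Hdac3 CKO cultures after 7 days in osteogenic medium. The table gave 25697 probe intensities per array. The median intensity was 97.1 to 97.2 on all 16 arrays and the highest was 37892 on each. The number of arrays limits the precision.

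Hdac3, the gene targeted by the knockout, was 0.891-fold as high in Hdac3 CKO as in wild type cultures. The mean log2 intensity was 10.42 ± 0.085 in wild type and 10.25 ± 0.077 in Hdac3 CKO (SD, n = 8 each), a difference of -0.17 (SE 0.045), and Hdac3 was lower in 5 of 5 runs. The exact permutation test gave p = 0.00249 over all arrangements of the arrays (smallest possible 0.000155). Within runs the exact permutation p was 0.00463 (smallest possible 0.00232). Over all 25697 probes the change did not pass in limma, with an adjusted p of 0.932, or of 0.162 with the runs as a block. With the level of the macrophage markers other than Fcer1g as a covariate beside the runs, the difference was -0.12 and its unadjusted limma p 0.0598. Hdac3 lies on chromosome 18 (37936971 to 37955015, GRCm38.p6). Whether its probe, ILMN_1220353, lies in the deleted exons is not known here, and the cultures also hold cells in which the Osterix promoter is not active.

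With the 5 runs as a block, the largest rise among the genes named by the rule was that of Hsd11b1, the enzyme that regenerates active glucocorticoid inside cells. Its mean log2 intensity was 7.81 ± 0.50 in wild type and 9.38 ± 0.81 in Hdac3 CKO (SD, n = 8 each), a 2.97-fold difference (log2 1.57, 95% interval 1.14 to 2.00, limma adjusted p = 0.00377). Adipoq, which encodes the fat cell hormone adiponectin, was 2.28-fold higher (log2 1.19, SE 0.13, adjusted p = 0.00105), and both genes were higher in 5 of 5 runs. Brinp3 fell the most, to 0.617-fold (log2 -0.70, SE 0.11, adjusted p = 0.0251), and the collagenase Mmp13 fell to 0.663-fold (adjusted p = 0.0251). Without a block no probe passed in limma: the smallest adjusted p was 0.300 (Ptprc), with 1218 probes at an unadjusted p under 0.05 where chance gives 1284.85, and the rank sum test also called 0 (1209 unadjusted).

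With the runs as a fixed block 56 of 25697 probes passed, 44 up and 12 down, whereas with the runs as a random block 0 passed (limma, 2043 at an unadjusted p under 0.05). The random block used 1 correlation between arrays of a run, 0.21, for all probes. For probes that differ much between runs, such as Adipoq, it leaves part of that difference in the spread. Of the 56, 45 had the same sign in all 5 runs. The 44 rising probes stand for 38 genes and the 12 falling ones for 12 genes, with 1 probe unnamed here. At an unadjusted p under 0.05 there were 2873 probes, 1492 up and 1381 down. The other genes named among those that rose were Serpina3n, an inhibitor of serine proteases (2.63-fold), haptoglobin (Hp, 2.09-fold), the melanocortin receptor partner Mrap (1.93-fold) and the amine oxidase Aoc3 (1.83-fold). G0s2, an inhibitor of fat hydrolysis, rose 1.78-fold and the glutamate transporter Slc1a3 1.72-fold. The transporters Slco2b1 and Slc4a8 rose 1.66-fold and 1.64-fold, and the lipid droplet protein gene Plin4 and the monooxygenase gene Fmo1 1.63-fold each. Their adjusted p ran from 0.00105 (Aoc3 and Slc1a3) to 0.0438 (Slc4a8). Among those that fell were the muscle phosphoglycerate mutase gene Pgam2 (0.684-fold), the cytokine gene Il11 (0.688-fold), the matrix protein gene Tnn (0.728-fold), the growth arrest gene Gadd45g (0.766-fold) and the heparin-binding growth factor gene Mdk (0.780-fold). The netrin receptor gene Unc5c, the cell division gene Cdc20, the uridine-cytidine kinase gene Uck2, Gabpb1 and Hoxd8 fell to between 0.799-fold and 0.831-fold. The brightest probes of Mmp13, Cdc20, Gadd45g and Uck2 did not pass (adjusted p = 0.0913, 0.455, 0.509 and 0.120), and that of Gadd45g was lower in 3 of 5 runs. Without a block Hsd11b1 and Adipoq had exact permutation p-values of 0.000622 and 0.254, and within runs both had 0.00232, the smallest possible.

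The number of called probes changed with single arrays: it was 12 without CKO15, 13 without WT13, WT14, CKO16 or WT21, 16 without WT42, 32 without CKO24 or CKO47, 34 without WT22 and 149 without WT30 or CKO32. Without run 2 it was 5 and with the mean of each run and genotype as 5 pairs it was 0 (limma, 2563 unadjusted), and with the macrophage marker level as a covariate 10, or 9 when Fcer1g was left out of that level. Hsd11b1, Adipoq, Mrap, Aoc3, G0s2 and Slc1a3 passed without any single array, whereas each of the other 6 rising and all 12 falling genes named here lost its call without at least 5 of the 16 arrays, with an adjusted p of up to 0.138. Adipoq, Aoc3 and Slc1a3 also passed without any single run (adjusted p = 0.0486 each without run 2), but lost the call with the 5 pairs (adjusted p = 0.178, 0.0522 and 0.0522) and with the runs as a random block (0.653, 0.616 and 0.624). Hsd11b1 lost its call without run 2 (difference 1.26, limma adjusted p = 0.0633), with the 5 pairs (0.299) and with the runs as a random block (0.136). With a factor for the 2 arrays that lack Y-linked RNA beside the runs 12 probes passed, 11 of them among the 56. These 2 are all wild type arrays of run 2, so the factor gives the same differences as leaving out run 2.

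**Figure D1:**
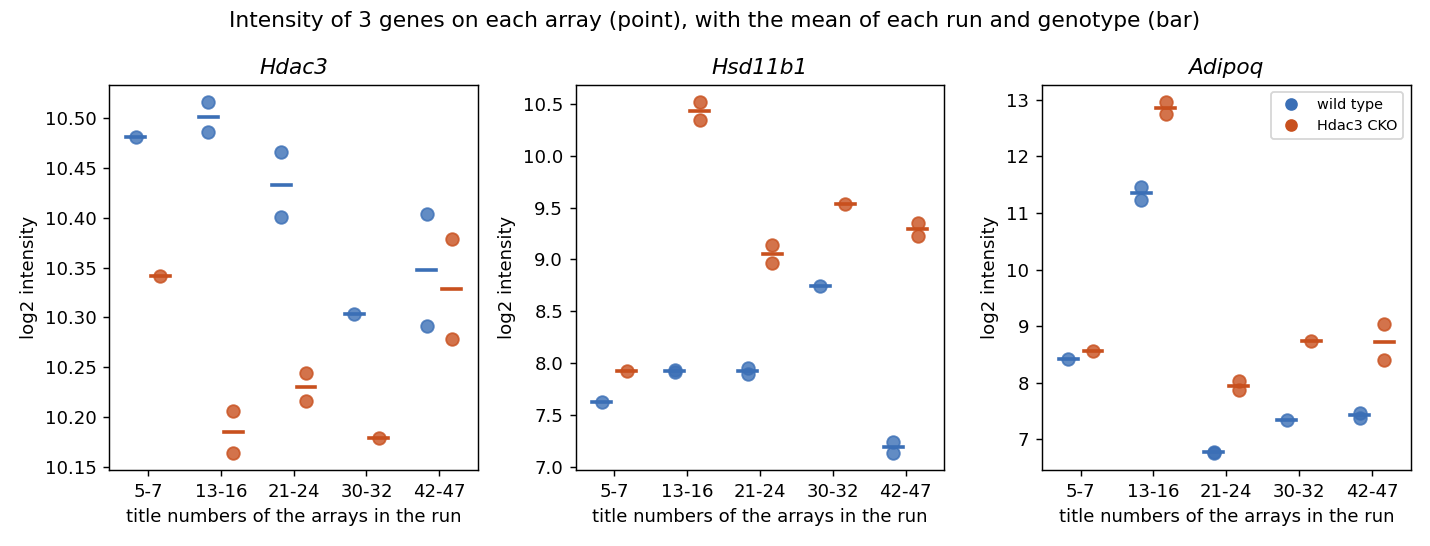
Log2 intensity (vertical axis) of Hdac3, Hsd11b1 and Adipoq on each array (points) by run, given by the title numbers of its arrays (horizontal axis), with blue for wild type, orange for Hdac3 CKO and a bar for the mean of each run and genotype. Hsd11b1 and Adipoq are higher and Hdac3 is lower in the Hdac3 CKO mean of 5 of 5 runs, and Adipoq differs more between runs than between genotypes.

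**Figure D2:**
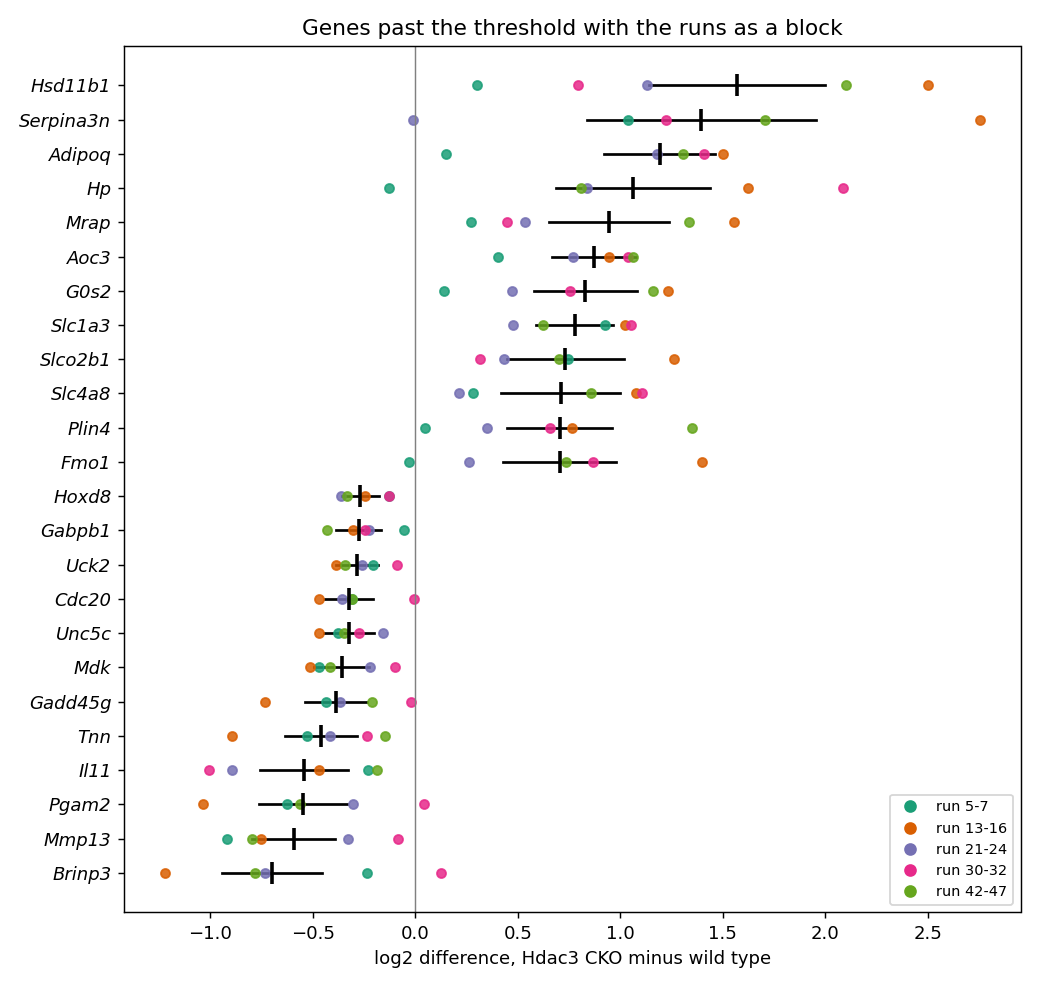
Log2 difference, Hdac3 CKO minus wild type (horizontal axis), of the 12 rising and 12 falling genes named by the rule, with a coloured point per run, a tick for the difference over all arrays and a black line for its 95% confidence interval with the runs as a block. Hsd11b1 has the largest difference, 1.57, and Brinp3 the largest fall, -0.70.

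Without a block the genes with the smallest p were Ptprc, Hsd11b1, Apbb1ip, Parp12, Lrrc25, Sema6b, Parp1, Ralgps2, Cpne1 and Ret among those higher in Hdac3 CKO cultures. Among those lower they were Gadd45g, Gabpb1, Pacsin3, Cdh2, Zfand1, Unc5c, Tnn, Hdac3, Brinp3 and Nsmce2. None of them passed, with adjusted p from 0.300 (Ptprc) to 0.932. Ptprc, which encodes the leukocyte antigen CD45, was 1.26-fold higher (SE 0.054 on the log2 scale) and passed with the runs as a block (adjusted p = 0.0251), as did Ret, a receptor tyrosine kinase gene (log2 0.58, adjusted p = 0.0251). Each lost this call without 6 of the 16 arrays, taken singly (adjusted p up to 0.0805 and 0.0818).

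Of the genes named whatever they showed, only Hsd11b1 and Adipoq passed with the runs as a block, and none passed without it. Cidec, a lipid droplet fusion gene, had a difference of 0.67 (SE 0.25, adjusted p = 0.300 with the block). CKO15 and CKO16 stood at log2 8.84 and 8.68 and no other array was above 6.43. The perilipin gene Plin1 had a difference of 0.38 (adjusted p = 0.236) and the adipogenic regulator Pparg one of 0.35 (adjusted p = 0.136). The glucocorticoid-responsive gene Fkbp5 had a difference of 0.25 (adjusted p = 0.0999). The osteoblast transcription factor gene Sp7 had a difference of -0.30 (adjusted p = 0.247) and Alpl, which encodes alkaline phosphatase, one of -0.45 (adjusted p = 0.163). Osteocalcin (Bglap, -0.076) and type I collagen (Col1a1, -0.039) had adjusted p of 0.895 and 0.938, and their sign turned in some settings. Osteoprotegerin (Tnfrsf11b) had a difference of -0.23 (adjusted p = 0.387), RANKL (Tnfsf11) one of -0.13 (0.571), Fabp4 one of 0.013 (0.962) and the phosphatase gene Phlpp1 one of 0.0080 (0.972), and the last of these and Fabp4 lay near background. Runx2 was not analysed here.

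The adipocyte list had a median difference above 0 (Hdac3 CKO minus wild type) in every run, but single members fell in some runs, such as Pparg in run 1 (log2 -0.25). Of its 17 measured members 15 were higher, with a median log2 difference of 0.25, and the list rose in camera at the preset correlation (adjusted p = 5.01e-04, and 4.81e-07 with the block) but did not pass with an estimated correlation (adjusted p = 0.817, and 0.210 with the block). Without run 2 the median was 0.073 (adjusted p = 0.00107 with the block). Over all probes 2 members rose with the block, Adipoq and the glycerol channel gene Aqp7 (1.62-fold, a call lost without 11 of the 16 arrays, taken singly, with an adjusted p up to 0.123), and 8 when adjusted over the list alone: Adipoq, Aqp7, Car3, Cebpa, Lep, Lpl, Pparg and Thrsp. None rose over the list alone without the block. The leptin gene Lep was 1.73-fold and the lipoprotein lipase gene Lpl 1.25-fold higher. A Lep probe stood at no less than log2 8.88 in CKO15 and CKO16 and at no more than 7.50 in the other arrays. Of 100 splits of the arrays within runs, 2 gave a p as small as the real one. The list was chosen partly from what is known of the study. The mean of the macrophage markers without Fcer1g differed by 0.69 in run 2 and 0.24 in run 5, where the median of the adipocyte list was 0.38 and 0.073. In runs 1, 3 and 4 it differed by 0.032, 0.016 and 0.026, where the median was 0.10, 0.038 and 0.10. With that mean as a covariate the adipocyte list had a median of 0.034 and an adjusted p of 0.138.

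Lipid storage genes rose as a list as well. Of 21 measured members 16 were higher, with a median log2 difference of 0.15 (camera adjusted p = 0.00429, and 1.03e-05 with the block). With an estimated correlation the list did not pass, at an adjusted p = 0.857 with an estimated correlation and an adjusted p = 0.338 with an estimated correlation and the block. G0s2 and Plin4 rose over all probes with the block. Adjusted over the list alone, 9 members rose, among them Dgat2, the enzyme of the last step of triglyceride synthesis (log2 0.54, SE 0.14), the lipase gene Pnpla2 (0.59, SE 0.17) and Fitm2, which acts in droplet formation (0.41, SE 0.10), and 1 fell, Hilpda (log2 -0.31, SE 0.10). The median was above 0 in 4 of 5 runs and highest in run 2 (0.56), and 3 of 100 splits within runs gave a p as small. Without a block the list lost its call without CKO15, CKO16 or WT30 (adjusted p = 0.110, 0.0720 and 0.0665, with a median of 0.078 without CKO15 and 0.092 without CKO16), and with the block it lost it with the macrophage marker level as a covariate (adjusted p = 0.179, and 0.588 without Fcer1g). Without CKO15 its median with the block was 0.10.

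**Figure D3:**
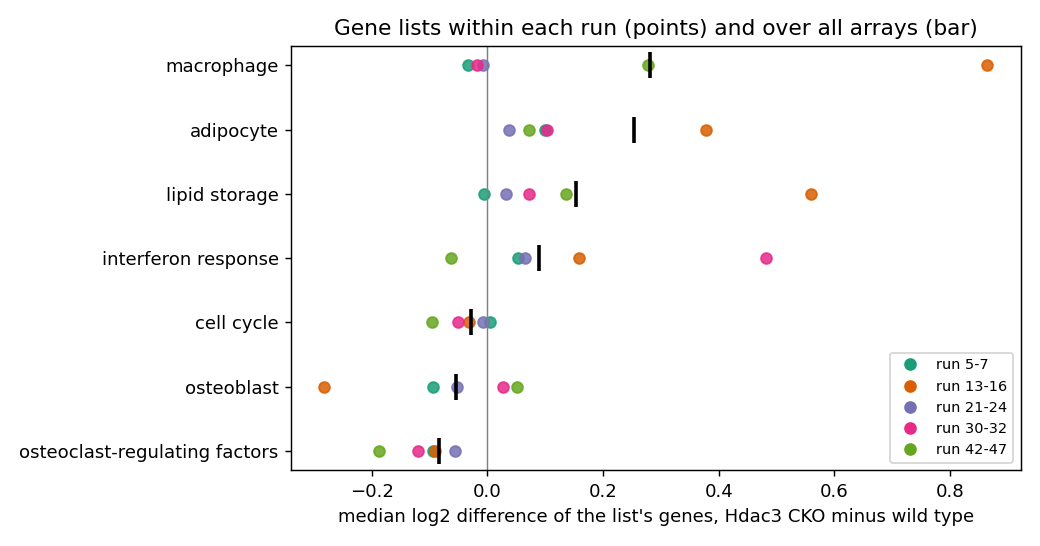
Median log2 difference of the genes of each list that passed with the runs as a block (horizontal axis), Hdac3 CKO minus wild type, within each run (points, coloured by run) and over all arrays (bar). The adipocyte list is above 0 and the osteoclast-regulating factors are below 0 in 5 of 5 runs, while the macrophage list reaches 0.86 in run 2 and is above 0 in 2 of 5 runs.

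Of the other lipid lists none passed. In fatty acid synthesis (adjusted p = 0.550 with the block) the desaturase gene Scd1 rose 1.62-fold over all probes (adjusted p = 0.0310), a call lost without 8 of the 16 arrays, taken singly (adjusted p up to 0.0982). Adjusted over the list alone, the desaturase gene Fads2 (log2 -0.31) and the elongase gene Elovl6 (log2 -0.26) fell. Cholesterol synthesis had an adjusted p of 0.0854 and fatty acid oxidation of 0.711, with no member passing over the list alone.

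The glucocorticoid list, of genes that activate or respond to glucocorticoid, had 10 of 15 measured members higher and a median of 0.033, and did not pass (camera adjusted p = 0.245, and 0.0619 with the block). Hsd11b1 rose over the list alone with and without the block, and 4 of its probes passed over all probes with the block. H6pd, which supplies the cofactor for the Hsd11b1 enzyme, rose 1.23-fold over the list alone (log2 0.30, SE 0.088), as did Fkbp5 (1.19-fold), each with the block only. The list was chosen partly from what is known of the study.

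Osteoclast-regulating factors, secreted signals that raise or lower osteoclast formation, had a median difference below 0 (Hdac3 CKO minus wild type) in 5 of 5 runs. Of 11 measured members 10 were lower, with a median log2 difference of -0.084. The list passed with the fixed block only (camera adjusted p = 0.00157, against 0.245 without it and 0.134 with a random block), had an adjusted p = 0.0940 with an estimated correlation and the block, and 1 of 100 splits within runs, the real one, gave a p as small. This share was not adjusted over the lists tested, so by itself it does not exclude chance. It also takes arrays of 1 run and genotype as separate cultures, which the labels do not say. Il11 fell over all probes, and Il11 and Wnt5a (0.769-fold, log2 -0.38, SE 0.075) fell over the list alone. Neither Tnfsf11 nor Tnfrsf11b passed.

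The osteoblast list was lower with the fixed block only (adjusted p = 0.0176, against 0.245 without it and 0.199 with a random block), with 13 of 19 measured members lower and a median of -0.054. Its adjusted p was 0.556 with an estimated correlation and the block, and 29 of 100 splits within runs gave a p as small. Ibsp, which encodes bone sialoprotein (0.682-fold, log2 -0.55, SE 0.13), and Alpl (0.733-fold, log2 -0.45, SE 0.12) fell over the list alone. The list was lower in 3 of 5 runs and most in run 2 (-0.28). Without run 2 its median was 0.016 (adjusted p = 0.916), and it lost its call without WT14 (adjusted p = 0.160) or CKO16 (adjusted p = 0.223, median -0.030). The call was also lost with the 5 pairs of run means (adjusted p = 0.0513), the Eif2s3y covariate (0.0865), the factor for the arrays that lack Y-linked RNA (0.874) and the macrophage covariate (0.894, and 0.986 without Fcer1g). Without a block the list passed in the opposite direction when WT13 and WT14 were left out (median 0.097, adjusted p = 0.0414) or given a factor (adjusted p = 0.0371). Either leaves run 2, which had the highest mean of Ibsp (log2 13.95), to Hdac3 CKO alone. This turn therefore cannot be told from a difference between runs. With the block, the median without WT5 or CKO7 was -0.033 and without CKO46 -0.092.

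The extracellular matrix list did not pass (adjusted p = 0.0619 with the block). Over the list alone Mmp13 (brightest probe, log2 -0.48), the proteinase inhibitor gene Timp1 (-0.23) and the proteoglycan gene Lum (-0.23) fell. Wnt signalling had an adjusted p of 0.0619, with the Wnt antagonist genes Nkd2 (log2 0.19) up and Notum (-0.22) down over the list alone. TGF-beta and BMP signalling had an adjusted p of 0.937. The chondrocyte list had one of 0.557, with Comp (log2 0.30) up and Col11a1 (-0.28) down over the list alone.

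Macrophage markers were higher in the Hdac3 CKO cultures of run 2 and run 5. Of 14 measured markers 12 were higher, with a median log2 difference of 0.28 (camera adjusted p = 0.00737, and 4.61e-05 with the block; adjusted p = 0.857 with an estimated correlation, and adjusted p = 0.343 with an estimated correlation and the block). Over the list alone 6 markers rose with the block, among them Cx3cr1 (1.46-fold), the mannose receptor gene Mrc1 (1.44-fold) and Adgre1 (1.35-fold), and Cd14 fell (log2 -0.22). The median was 0.86 in run 2, 0.28 in run 5 and between -0.034 and -0.0082 in the others, and 15 of 100 splits within runs gave a p as small. Without run 2 the list did not pass with the block (median 0.051, adjusted p = 0.420), and without a block it did not pass without WT13 (adjusted p = 0.214, median 0.18), WT14 (0.0570, median 0.17) or CKO46 (0.0965, median 0.17). Without both WT13 and WT14 its median was 0.028 (adjusted p = 0.876), and 0.872 was the adjusted p with a factor for them. Either leaves run 2 to Hdac3 CKO alone. In run 2 the wild type arrays also lacked Y-linked RNA: Eif2s3y stood at log2 5.89 and 6.17 in WT13 and WT14 and at 9.75 and 9.78 in CKO15 and CKO16, while no other array was below 8.28. That value was from CKO32 of run 4, against 9.78 in WT30 of the same run. Xist was highest in WT14 and WT13 (7.95 and 7.82), followed by CKO32 (7.63). Fcer1g stood at no more than 6.20 in WT13 and WT14 and at no less than 11.73 in the other 14 arrays. The values of the macrophage list given here include Fcer1g.

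Interferon response genes had a median difference above 0 (Hdac3 CKO minus wild type) in 4 of 5 runs. Of 21 measured members 20 were higher, with a median of 0.089 (camera adjusted p = 0.00737, and 7.15e-05 with the block; adjusted p = 0.943 with an estimated correlation, and adjusted p = 0.387 with an estimated correlation and the block). The antiviral genes Oas2 (1.35-fold, log2 0.43, SE 0.099) and Oasl2 (1.34-fold, log2 0.42, SE 0.11) rose over the list alone with the block. The median was 0.48 in run 4, which holds 1 array per genotype, and -0.063 in run 5. Without a block the list lost its call without CKO15 (adjusted p = 0.285), CKO16 (0.0720), WT30 (0.0980), CKO32 (0.0714), WT22 (0.0659) or WT44 (0.0804), and with the probes above the median alone (0.0834). The median was 0.026 without CKO15, and 0.14 without CKO24, CKO46 or CKO47, and with the block 0.056 without WT30 or CKO32. Of 100 splits within runs, 32 gave a p as small.

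Cell cycle genes were lower as a list with the fixed block (adjusted p = 0.0322, against 0.245 without it and 0.186 with a random block), with 15 of 22 measured members lower, a median of -0.029 and no member passing over the list alone. The adjusted p was 0.338 with an estimated correlation and the block, and 10 of 100 splits within runs gave a p as small. Without a block the list passed without CKO7 (adjusted p = 0.0276), CKO23 (0.0389) or CKO24 (0.0232), without WT13 and WT14 (0.00449) and with a factor for them (0.00375), and its median ran from -0.091 without CKO24 to -0.0074 without CKO46. With the block the list lost its call without WT30 or CKO32 (adjusted p = 0.0912 each), WT44 (0.106) or CKO46 (0.110), without run 5 (0.288), with array weights (0.0626) and with the macrophage covariate without Fcer1g (0.131). The median was -0.013 without CKO46 and between -0.053 and -0.044 without WT5, CKO7, WT14, WT21 or CKO24. In p53 and DNA damage 16 of 17 members were lower, and the list did not pass (adjusted p = 0.0619 with the block).

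The remaining lists did not pass, with or without the block. Their adjusted p with the block was 0.937 for histone deacetylases and Hdac3 corepressors, 0.767 for the circadian clock and 0.552 for cell stress. Among markers of other cell types it was 0.557 for osteoclasts, 0.0945 for neutrophils, 0.946 for lymphocytes, 0.685 for mast cells, 0.920 for erythroid cells and megakaryocytes, 0.0945 for endothelial cells, 0.136 for smooth muscle and pericytes and 0.628 for skeletal muscle. Desmin (Des, log2 0.31) rose and the mast cell gene Ms4a2 (log2 -0.14) fell over their lists alone. In all, 4 of 27 lists passed without a block, 7 with the fixed block, 4 (all higher) with the runs as a random block, and 0 with an estimated correlation in either fit (camera, with 2 and 6 lists at an unadjusted fry p under 0.05). Without a block 2 lists passed without CKO15, CKO16 or WT30. With the block 11 passed without WT30, CKO32, WT22 or WT42, and 13 without WT21 or CKO24.

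The arrays grouped by run before they grouped by genotype. The first principal component held 26.6% of the variance, of which the runs accounted for 94.5% and genotype for 0.822%. The second held 24.2%, with 87.5% for runs and 7.86% for genotype. Bone and fat genes differed between runs: the mean log2 intensity of Ibsp was 13.95 in run 2 and 10.06 in run 5, and that of Adipoq in wild type was 11.35 in run 2 and 6.77 in run 3. In each run the wild type mean was closest to the Hdac3 CKO mean of its own run, with correlations of their deviations across genes from 0.412 to 0.744, against at most 0.262 with another run. Genes are not independent replicates.

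**Figure D4:**
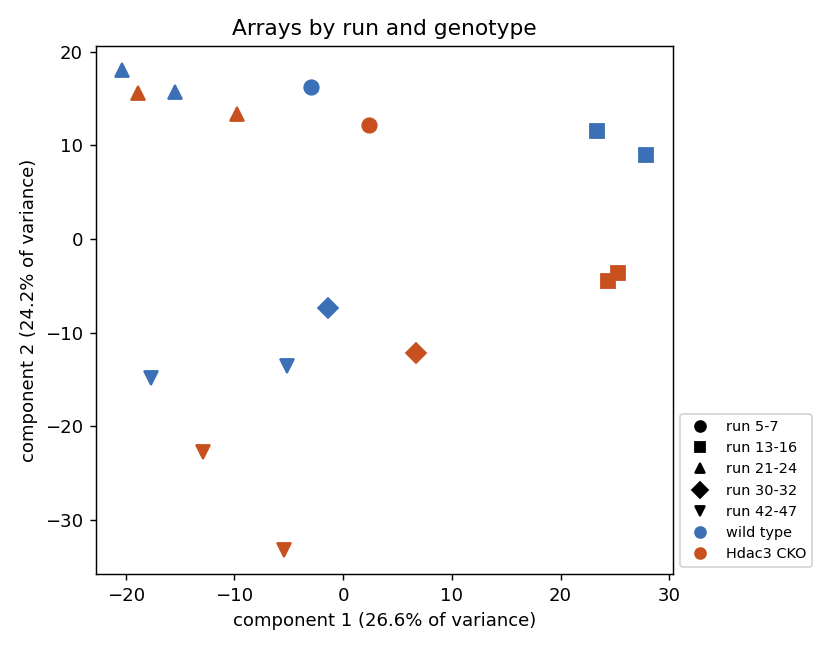
Scores of the 16 arrays on the first principal component (horizontal axis, 26.6% of variance) and the second (vertical axis, 24.2%), with a symbol per run and blue for wild type or orange for Hdac3 CKO. Arrays of 1 run lie near each other, and the arrays of run 2 (13 to 16) have the highest scores on the first component.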

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

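Chosen only after the result was seen were the splits of the probe count without a block, the splits for the macrophage and interferon lists, the adipocyte median within runs, every test without run 2, every macrophage covariate test, every test that leaves out Fcer1g, the test in runs 1, 3 and 4, whose limit was also set again after its value was seen, and the tests that exchange genotype in whole runs.

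Of 192 groups of 8 arrays checked, 4 held an array whose gap to the next one was too large a share of the group's range by Dixon's test, where chance gives about 1 in 20. Fkbp5 in WT30 stood at log2 11.32 against 10.43 to 10.73 in the other wild type arrays (gap 0.664 of the range). Gadd45g in WT30 stood at 10.19 against 10.49 to 10.73 (gap 0.548). Nsmce2 in CKO47 stood at 8.52 against 8.81 to 9.03 in the other Hdac3 CKO arrays (gap 0.569). Oas1a in WT5 stood at 6.60 against 6.20 to 6.36 (gap 0.591).

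Splits of the 16 arrays put bounds on the counts. Without a block the real count was 0 (limma; 1218 probes at an unadjusted p under 0.05, and 0 by the rank sum test), which 100 of 100 splits reach whatever they hold, so the splits decide nothing there. The highest other split, which mostly parted the runs, gave 190. With the runs as a block 4 of 100 splits gave as many as the real 56, and the highest others gave 338 and 207. That share lies just under 0.05 and rests on a sample of the splits, so by itself it does not exclude chance. On the 5 pairs of run means, or with the runs as a random block, 0 probes passed. The share counts against chance only if arrays of 1 run and genotype are separate cultures, which the labels do not say. With such arrays kept together, genotype exchanged in whole runs gives 16 arrangements, too few for a share under 0.05 (real 56, highest other 30; 1 of 16 reached the real count, the real one itself). The splits with 338 and 207 point to a structure of the arrays within runs, which was not identified. For the lists, 69 of 100 splits gave as many as the real 4 without a block (highest other 16) and 23 of 100 as many as the real 7 with it (highest other 15), so chance cannot be excluded for the number of lists. Besides the real split, 87 splits without a block and 80 with it called at least 1 list at the preset correlation. A small camera p at that correlation therefore does not by itself exclude chance. Exchanged in whole runs, 13 of 16 arrangements gave as many lists as the real 7 (highest other 15). The real number of lists was thus not unusual there, although 16 arrangements could not have given a share under 0.05.

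For the higher adipocyte list 2 of 100 splits within runs gave a p as small (real 1.78e-08, smallest other 1.13e-08). This share was not adjusted over the lists tested, so by itself it does not exclude chance. It also counts against chance only if arrays of 1 run and genotype are separate cultures, which the labels do not say. The list did not pass with an estimated correlation (adjusted p = 0.817, or 0.210 with the block). Exchanged in whole runs, 16 arrangements are too few for a share under 0.05, and 2 of them, the real one and the exchange of run 3 alone, gave a p as small (1.78e-08 and 1.13e-08). The median of the adipocyte list was above 0 in 5 of 5 runs. Each run holds as many arrays of either genotype, so a difference between runs alone could not raise the list, and this count does not test it. Without run 2 the adjusted p was 0.00107 (camera at the preset correlation) with a median of 0.073, so a smaller rise remained. A p at that correlation does not by itself exclude chance. The remaining rise therefore argues against the missing Y-linked RNA of WT13 and WT14 as the whole cause only if it is not chance. A higher share of macrophages in Hdac3 CKO cultures stays a candidate explanation: with the mean of all 14 markers as a covariate the adjusted p was 0.0200, but Fcer1g, near background in WT13 and WT14 alone, distorts that mean, and without it the adjusted p was 0.138, as the median went from 0.25 (quartiles 0.020 to 0.37) to 0.034 (quartiles -0.044 to 0.17) and the median SE only from 0.089 to 0.098. In runs 1, 3 and 4, where the marker level differed by at most 0.032, 13 of 17 genes were higher (median 0.055, below the median SE of 0.082). The camera adjusted p was 0.00917 (0.519 with an estimated correlation, 0.0216 unadjusted) and the list mean rose by 0.13 (95% interval 0.067 to 0.19). Adipoq alone differed by 0.15, 1.18 and 1.41 in these runs, so the mean rests in part on it. The rise of the mean argues against macrophage content as its whole cause there only if the arrays are separate cultures. For runs 2 and 5 macrophage content stays open, as does an effect of Hdac3 loss.

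The higher macrophage list may be chance, since 15 of 100 splits within runs gave a p as small (real 5.12e-06, smallest other 3.10e-09). It may also belong to run 2, where the wild type arrays alone lack Y-linked RNA, since without run 2 the adjusted p was 0.420; whether sex, genetic background or another difference of those cultures lies behind this was not tested. Whether a higher share of macrophages with an unchanged profile lies behind the list is not decided by the markers. Relative to the marker mean 0 of 14 markers changed. With Fcer1g left out, a test chosen after the values were seen, 4 of 13 did. Cd14 (-0.47, SE 0.10) and Msr1 (-0.30, SE 0.093) were lower. Mrc1 (0.29, SE 0.099) and Cx3cr1 (0.30, SE 0.11) were higher. Fold changes of dim probes are compressed, so under a higher share alone markers of different brightness need not shift equally. The SEs also take arrays of the same run and genotype as separate cultures, which the labels do not say. A change in the macrophages themselves stays open and was not tested.

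The higher interferon list may be chance, since 32 of 100 splits within runs gave a p as small (real 1.06e-05, smallest other 7.93e-11). A higher share of macrophages as the whole cause has values against it: with the marker mean as a covariate the adjusted p was 0.0119, and 0.0181 with Fcer1g left out, with medians of 0.090 and 0.094 against 0.089 before. With a correlation between genes estimated from the data the list did not pass (adjusted p = 0.387 with the run block, 0.943 without). An effect of genotype stays open and was not tested apart from these.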

How the results depend on the processing

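Every setting run together with the run block, every covariate, the factor for the arrays that lack Y-linked RNA, the omission of runs or of the wild type arrays of run 2, and the 5 pairs were chosen after seeing the data. Except where a construction is given, the cause of a change was not tested.

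The 0 probes called without a block stayed 0 in 33 of 34 other settings, among them a random run block, a block by the order of the sample records and single arrays left out (0 to 0), and became 56 with the fixed run block (limma; 1218 probes at an unadjusted p under 0.05 and 0 by the rank sum test). Some of these settings could not change the count: stricter thresholds add no calls, and a floor of 1 lies below every intensity. Hdac3 was lower in 30 of 30 other settings, and in 35 of 35 with the block, -0.19 to -0.15 with single arrays left out in either fit. The difference was -0.12 without run 2, with the factor for the arrays that lack Y-linked RNA beside the runs and with either macrophage covariate, and only with the covariate without Fcer1g did its unadjusted limma p exceed 0.05 (0.0598). With the run block the 56 called probes became 62 without run 1, 5 without run 2 (4 shared), 12 with the factor (11 shared), 15 without run 3, 149 without run 4 (53 shared) and 20 without run 5. They became 10 with the macrophage covariate, 9 without Fcer1g (7 shared), 11 at an adjusted p under 0.01, 116 under 0.10, 22 when at least 1.5-fold, and 0 with the 5 pairs of run means. Single arrays left out gave 12 to 149: 12 without CKO15, 13 without WT13, WT14, CKO16 or WT21, 16 without WT42, 32 without CKO24 or CKO47, 34 without WT22 and 149 without WT30 or CKO32, which alone of their genotype in run 4 take the run out of the comparison. The 16 settings that stayed near it, some with single arrays left out, gave 50 to 67.

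The 4 lists called without a block became 7 with the fixed run block, stayed 4 with the random one, 7 without WT13 and WT14 or with a factor for them (either leaves run 2 to Hdac3 CKO alone), 0 with an estimated correlation, and 2 (without CKO15, CKO16 or WT30) to 5 with single arrays left out. The 7 lists called with the block became 13 without run 3, 11 without run 4, 3 with the macrophage covariate without Fcer1g, 0 with an estimated correlation, and 6 to 13 with single arrays left out: 11 without WT30, CKO32, WT22 or WT42 and 13 without WT21 or CKO24.

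Some signs turned. Without a block, array weights gave Bglap 0.19, Col1a1 0.036 and Phlpp1 -0.0078. Without WT13 and WT14, or with a factor for them, the osteoblast list had a median of 0.097 and passed as higher (adjusted p = 0.0414 and 0.0371), Bglap 0.57, Col1a1 0.27, Ibsp 0.22 and Phlpp1 -0.012. Run 2 is then left to Hdac3 CKO alone, so these turns cannot be told from a difference between runs. With single arrays left out Bglap ran from -0.42 to 0.22, Col1a1 from -0.16 to 0.12, Fabp4 from -0.016 to 0.029, Phlpp1 from -0.0058 to 0.023 and the osteoblast list from -0.10 to 0.051. With the run block, single arrays left out gave Bglap -0.17 to 0.016, Col1a1 -0.12 to 0.030, Fabp4 -0.014 to 0.039 and Phlpp1 -0.0083 to 0.027. Array weights gave Phlpp1 -0.0047. Leaving out run 1 gave Bglap 0.016, and run 2, or the factor, gave Col1a1 0.10, Phlpp1 -0.010 and the osteoblast list 0.016. Leaving out run 3 gave Col1a1 0.00091, run 4 Fabp4 -0.014 and run 5 Phlpp1 -0.027. The 5 pairs gave Col1a1 0.015 and Phlpp1 -0.013, and the Eif2s3y covariate Col1a1 0.037. The macrophage covariate gave Col1a1 0.13, Phlpp1 -0.027 and the macrophage list -0.023, the covariate being built from that list. Without Fcer1g it gave Col1a1 0.15, Phlpp1 -0.039, Cidec -0.085, the osteoblast list 0.038 and the macrophage list -0.049.

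Of 2100 pairs of a named gene and a setting without a block, 2047 stayed the same. No gene passed there to begin with, so the same means only an unchanged sign and still no call. With the block 2015 of 2440 did, 365 were weaker, 32 stronger, and 28 turned. The block by the order of the sample records was not run with the run block, since it is nested in it, and the sex covariate was not run in the form set down, since only wild type held arrays without Y-linked RNA. Fabp4 (mean log2 6.18 in wild type) and Phlpp1 (6.41) are dim, so their small differences do not bound a change.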

Other observations

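The acute phase, lysosome, ribosome biogenesis and Hox lists, like the search for probes with a gap, were chosen only after the values were seen, so tests of these lists decide nothing and only their values are given.

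All 12 measured acute phase genes were higher in Hdac3 CKO cultures, with a median log2 difference of 0.28, above 0 in 4 of 5 runs. Of lysosome genes 14 of 16 were higher, with a median of 0.096, above 0 in 5 of 5 runs. Of ribosome biogenesis genes 19 of 23 were lower, with a median of -0.13, below 0 in 5 of 5 runs. Of 38 Hox genes 21 were higher and 17 lower, with a median of 0.017, among them Hoxb4 (0.40, SE 0.12), Hoxb5 (0.33, SE 0.055) and Hoxd8 (-0.27, SE 0.043).

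A search for probes whose arrays fall into sets more than 1.2 log2 units apart, with the lower set below 9 and its lowest array below 7, found 20 probes. In 10 of them the gap parted wild type from Hdac3 CKO arrays within a run, and in 0 of 20 did it part any of the 6 pairs of arrays that share run and genotype. Fcer1g was low in WT13 and WT14 alone, with a gap of 5.53. Cidec, Lyve1, Ffar2, Chodl, Car3 and Lep were high in CKO15 and CKO16 alone, with gaps of 1.38 (Lep) to 2.59 (Ffar2), and Zfp330 was high in CKO46 and CKO47 alone (gap 2.20). Arrays of 1 run and genotype had a median correlation of 0.994 across probes (6 pairs), against 0.992 for arrays of 1 run and different genotype (14 pairs) and 0.985 for arrays of 1 genotype in different runs. Whether such arrays hold cells of separate animals is not given in the sources used here.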
